A study of Mus musculus with 6 samples.

How the data were processed

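Total RNA from articular cartilage of 3-month-old C57BL/6 mice was measured by bulk RNA sequencing in 2 genotypes, Cry2-knockout (KO) and wild-type (WT), with 3 libraries each. The labels describe 2 ways of extracting RNA from cartilage and name the mouse tissue with the TRIzol one alone, so which steps applied to these libraries, and how the tissue was parted from bone, is uncertain. Libraries were made with the SMART-Seq v4 Ultra Low Input kit, which does not mark the strand, so reads of overlapping and antisense genes cannot be told apart. The deposited values are raw counts of reads per gene symbol, which the authors made with Trim Galore, STAR and featureCounts on the mouse build mm9. DESeq2 is also named in their processing notes, but the counts as deposited are whole numbers with unequal totals and are not normalised. The versions, the annotation and the treatment of reads that match several places are not given in the sources used here. Globin genes and Eno1 had 0 to 4 reads in every library and Gapdh, named after its values were seen, 56 to 76, so genes with near-identical copies are uncertain.

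Each file listed 24015 gene symbols and 1 blank line, which was left out. Library totals were 13695681 to 16743928 reads, so 1 gene with 0 reads would allow a level of up to 0.179 to 0.219 CPM (3 reads of the total). Reads without molecular identifiers are not independent molecules, and such limits cover counting error only. The 10 most abundant genes held 10.9 to 14.5% of reads. Sex was read from Xist and 4 Y-linked genes, as the labels do not give it, and neither do they give the time of day at which tissue was collected.

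Groups were taken from the labels. Genes were tested in edgeR 4.0.16 under R 4.3.3 after filterByExpr (minimum count 10, minimum total 15), which kept 15107 genes, with TMM scaling (factors 0.967 to 1.05). The quasi-likelihood test was two-sided, with genotype as the sole term and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p under 0.05. Fold changes are KO over WT on the log2 scale, levels are CPM as edgeR computes it from TMM-scaled library sizes, and standard errors were derived from the fold change and the F statistic. Levels per list and library are means of log2 CPM with a prior count of 2.

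Before the data were examined, 29 lists of genes were fixed. The 15 pathway lists were clock repressors and outputs, clock activators and regulators, cartilage matrix and its regulators, superficial zone, hypertrophy, matrix proteases and inhibitors, fibrous matrix and small proteoglycans, TGF-beta and BMP signalling, inflammatory mediators, immediate early genes, hypoxia and glycolysis, the unfolded protein response, the respiratory chain, ribosomal proteins and the cell cycle. The 14 marker lists were those of osteoblasts and osteocytes, osteoclasts, erythroid cells, neutrophils and myeloid precursors, B cells, T cells, macrophages, skeletal muscle, adipocytes, endothelium, synovial and connective tissue fibroblasts, tendon and ligament, smooth muscle and pericytes, and Schwann cells. Some genes stand in more than 1 list, among them Col1a1 and Fmod. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the 29 lists, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

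The genes named were fixed by a rule. Cry2 came first, then the 10 genes with the largest change in each direction among those past the adjusted threshold, with a mean of at least 5 CPM and no overlap between groups. As no gene passed, these were replaced by the 5 genes per direction with the smallest unadjusted p among genes with a mean of at least 5 CPM. From each list came the members past the threshold or, failing those, the 2 with the smallest p, and every member of both clock lists. This gave 85 genes, of which 3 are not reported here, and any other gene is said to have been chosen after its values were seen.

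Genes near Cry2 were to be counted within 20 Mb, with 10 and 40 Mb as alternatives, but no annotation of mm9 was at hand. The plan for that case named 200 genes on each side by gene order, read here as tested genes. These, in the gene order of GRCm38.p6, were compared with the genes elsewhere by Fisher's exact test (two-sided). Of the 24015 symbols, 22508 matched a symbol of that annotation, 1368 an older name and 139 neither.

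Alternatives planned were DESeq2 1.42.0, limma-voom, other scalings and filters, the replicate number as a block, 1 surrogate variable from sva 3.50.0, leaving out each library in turn, and removing erythroid, neutrophil, B cell and muscle markers before scaling. Sex, muscle, Ckm and adipocyte levels as covariates, leaving out the 3 libraries high in muscle markers, other forms of the quasi-likelihood fit and other numbers of neighbours were added after the data were seen. The adipocyte level was higher in every KO library than in every WT library. As a covariate it can take up much of the genotype difference, so lists lost or turned with it do not show fat content as the cause. The edgeR and DESeq2 steps were tested on simulated counts of 15107 genes with the same means, totals and dispersions. In these, 200 genes with a mean of at least 5 CPM were changed 2- or 4-fold. The 18 genes of the unfolded protein response list were raised 1.5-fold. Each gene was drawn independently, without the differences in sex, muscle and fat markers between the real libraries. The shares recovered may therefore be too high for the real data. edgeR recovered 69% of genes changed 2-fold and 98% of those changed 4-fold, with 12 calls among 14889 unchanged genes. DESeq2 recovered 86% and 97%, with 47 such calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.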

Results

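Articular cartilage, the tissue that covers the ends of bones in a joint, was compared between Cry2-knockout (KO) and wild-type (WT) mice. The question was which genes differ in level once Cry2, a transcriptional repressor of the circadian clock, is lost. By the labels, the tissue came from the knee surfaces of the femur and tibia of 3-month-old C57BL/6 mice, with 3 libraries per genotype. The 6 libraries held 13695681 to 16743928 reads assigned to genes, and 20085 to 21086 of the 24015 gene symbols had at least 1 read in a given library. Xist, the RNA that silences an X chromosome in females, stood at 247 CPM (reads scaled to library size) in WT replicate 1 and at 206 and 216 CPM in KO replicates 1 and 2. In the other 3 libraries it was at 0.716 to 0.865 CPM, and 4 Y-linked genes summed to 265 to 284 CPM there. By these genes WT held 1 female and 2 male libraries and KO 2 female and 1 male. The labels do not say that the replicates were separate animals. Libraries of both sexes show more than 1 animal per genotype, but those of the same sex may share one, so the p-values measure only the spread between these samples, which may be technical in part. Transcripts of skeletal muscle also set libraries apart within both genotypes. The muscle creatine kinase Ckm, named after its values were seen, was at 505 to 542 CPM in WT replicate 2 and KO replicates 2 and 3, and at 33.9 to 78.9 CPM in the other 3 libraries.

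Cry2 itself was lower in every KO library than in every WT library. Its level was 114 ± 18.3 CPM (SD, n = 3) in WT and 61.9 ± 1.90 CPM (SD, n = 3) in KO, a log2 fold change of -0.89 (SE 0.13). The KO libraries lay between 60.6 and 64.0 CPM, from 894 to 1017 reads, and the WT libraries between 94.6 and 131 CPM, from 1452 to 1874 reads. Over all genes this difference did not pass edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (adjusted p = 0.554), whereas DESeq2 gave an adjusted p of 2.29e-05, and over the 24 alternatives the adjusted p ranged from 2.29e-05 to 0.9999. A count over the whole gene also holds reads from any exons outside the deleted part, so the remaining KO reads do not show how much functional transcript was left.

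Among clock genes, the list of repressors and outputs was higher in KO as a group, and the list of activators and regulators was lower as a group. Nr1d1, which encodes the nuclear receptor REV-ERBα that represses Arntl, was at 26.0 ± 10.7 CPM in WT and 128 ± 28.7 CPM in KO (SD, n = 3 each), 4.91-fold higher. Dbp, a transcription factor of clock output, was at 9.51 ± 7.62 CPM in WT and 52.2 ± 13.3 CPM in KO, 5.47-fold higher. The fixed list of clock repressors and outputs rose as a group, with a median log2 fold change of 0.47 and 10 of its 12 members higher (camera with Benjamini-Hochberg adjustment, adjusted p = 3.02e-15). This call was lost with an estimated correlation between genes (adjusted p = 0.111 with an estimated correlation). Of the 12 members, 7 passed edgeR's quasi-likelihood test adjusted over the list alone, all higher in KO, and 0 passed over all genes tested. These 7 were Nr1d1, Dbp, Nr1d2 (log2 fold change 0.98, SE 0.17), Ciart (0.92, SE 0.30), Tef (0.62, SE 0.14), Per3 (0.50, SE 0.18) and Per2 (0.44, SE 0.11). Of the other members, Hlf had a log2 fold change of 0.35, Bhlhe40 of 0.29, Per1 of 0.21, Bhlhe41 of -0.071 and Cry1, the paralog of Cry2, of -0.13.

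The list of clock activators and regulators fell as a group, with a median log2 fold change of -0.29 and 10 of 12 members lower (camera adjusted p = 0.00497; adjusted p = 0.344 with an estimated correlation). None of its members, 0 of 12, passed edgeR's test adjusted over the list alone or over all genes. Arntl, which encodes the core activator BMAL1, had 31.9 ± 12.5 CPM in WT and 15.7 ± 6.14 CPM in KO (SD, n = 3 each), a log2 fold change of -1.02 (SE 0.35). Its partners Clock and Npas2 had log2 fold changes of -0.29 (SE 0.094) and -0.67 (SE 0.32). Nfil3, Fbxl21, Rora, Csnk1d and Timeless followed at -0.39, -0.36, -0.28, -0.026 and -0.0064, and Csnk1e and Rorb were at 0.13 and 0.41. Without WT replicate 1 the list's camera adjusted p was 0.0725, and with the adipocyte markers as a covariate its median was -0.097 (camera adjusted p = 0.123). The adipocyte level separates the genotypes, so that covariate may itself remove a genotype difference. Within sexes its median was -0.37 in females and -0.072 in males. Within the libraries of each sex the log2 difference of Nr1d1 was 2.22 in females and 2.64 in males, and that of Dbp 3.04 and 2.80. Within libraries low and high in muscle transcripts it was 2.10 and 2.90 for Nr1d1 and 2.26 and 3.39 for Dbp.

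**Figure D1:**
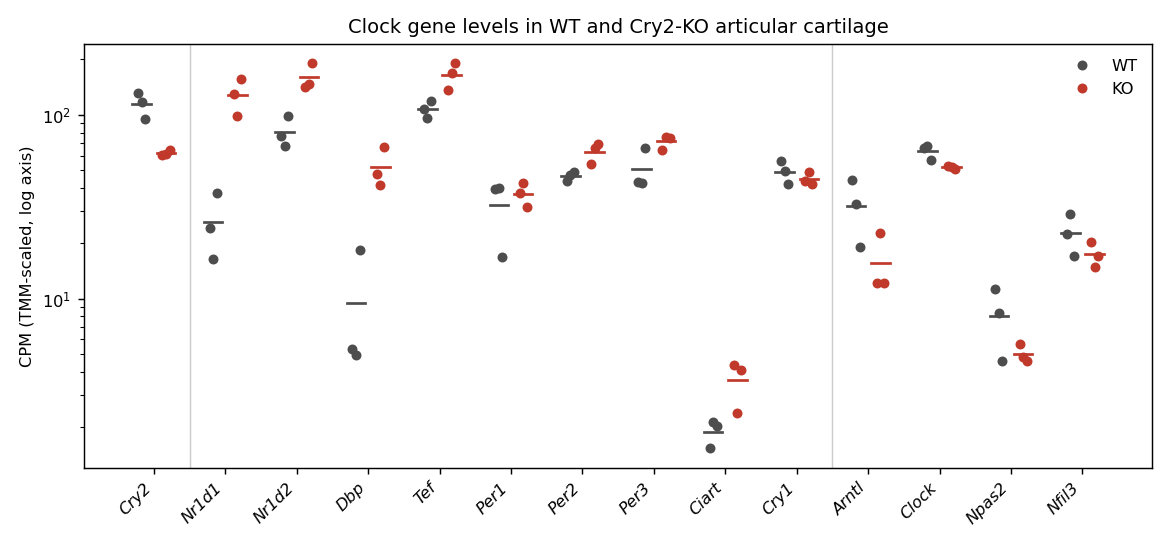
Levels of clock genes in each library, in CPM on a log axis, with WT in grey, KO in red, 3 libraries each and lines at the group means. The 3 KO libraries of Nr1d1 lie between 98.5 and 156 CPM, above the WT libraries at 16.4 to 37.5 CPM, while those of Cry2 lie below all WT libraries.

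Across the transcriptome, the genes with the strongest evidence of a difference were a small mixed group led by Rbm45 and the clock genes. Rbm45, which encodes an RNA-binding protein, was at 4.75 ± 0.580 CPM in WT and 18.7 ± 4.08 CPM in KO (SD, n = 3 each), 3.93-fold higher, with the smallest p of all genes. Among genes with a mean of at least 5 CPM, the next smallest p-values of the higher genes, after Nr1d1, belonged to Nfatc2, a calcineurin-regulated transcription factor (36.5 to 69.2 CPM), Col4a1, a basement membrane collagen (70.7 to 110.1 CPM), and Nr1d2 (80.9 to 159.5 CPM). Those of the lower genes, after Cry2, belonged to Sertad4 (147 to 75.0 CPM), Ihh (47.5 to 32.0 CPM), Olfm4 (37.0 to 19.1 CPM) and Medag (70.9 to 41.5 CPM). Ihh encodes Indian hedgehog, the signal of prehypertrophic chondrocytes. In each of these 10 genes the KO and WT libraries did not overlap, as in 1659 of the 15107 genes tested, or 10.98%, where chance gives 10%.

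None of the named genes passed the threshold over all genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 15107 genes had an adjusted p under 0.05, and the adjusted p of Rbm45 was 0.175. At an unadjusted p under 0.05 there were 930 genes, 616 higher and 314 lower in KO, against 755 that no effect at all would give. DESeq2 called 50 genes, 42 higher and 8 lower, among them Rbm45, Nr1d1, Nr1d2, Dbp, Tef, Cry2, Sertad4 and Ihh, and limma-voom called 0 with 932 at an unadjusted p under 0.05. On the simulated counts DESeq2 made 47 calls among 14889 unchanged genes and edgeR 12. The 47 came beside 86% and 97% of the genes changed 2- and 4-fold, which DESeq2 recovered. They do not give the share of the 50 calls that is false, but calls by DESeq2 alone remain weak evidence. The count of 930 varied when 1 library was left out, which also lowers the power of the test. Without WT replicates 1 to 3 it was 792, 543 and 1714, the last as 885 higher and 829 lower. Without KO replicates 1 to 3 it was 649, 544 and 1379. With the adipocyte markers as a covariate it was 268, 194 higher and 74 lower, and with the muscle markers 1426. Without the 3 libraries high in muscle transcripts, a comparison of 2 WT libraries with 1 KO library whose spread is assumed to be that of WT, edgeR called 51 genes, 44 higher and 7 lower. This setting was added after the data were seen.

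Markers of fat and of blood vessels were higher in KO, together with markers of bone-forming and bone-resorbing cells. The adipocyte list had a median log2 fold change of 1.39, or 2.62-fold, with 10 of 10 members higher (camera adjusted p = 3.02e-15; adjusted p = 0.218 with an estimated correlation). Of its 10 members 9 passed edgeR's test adjusted over the list alone and 0 over all genes. Cidec, a lipid droplet protein, was at 4.67 ± 1.08 CPM in WT and 18.2 ± 9.03 CPM in KO, and Cfd, the adipokine adipsin, at 73.2 ± 17.3 and 235 ± 134.9 CPM (SD, n = 3 each). The endothelial list had a median of 0.61 with 11 of 11 members higher (camera adjusted p = 3.22e-14; adjusted p = 0.342 with an estimated correlation). In it 6 of 11 members passed adjusted over the list alone and 0 over all genes. Tek, the angiopoietin receptor of endothelium, was at 8.81 ± 1.55 and 21.0 ± 5.63 CPM, and its relative Tie1 at 11.9 ± 2.15 and 21.1 ± 4.32 CPM in WT and KO. These differences were carried mainly by KO replicates 1 and 2, the female KO libraries. The mean log2 CPM of the adipocyte markers was 5.22 and 5.50 there and 4.21 in KO replicate 3, against 3.58 to 3.89 in WT. That of the endothelial markers was 4.93, 4.71 and 4.24 in KO replicates 1 to 3 and 3.83 to 4.24 in WT. Within sexes the median log2 difference of the adipocyte list was 1.61 in females and 0.48 in males, and that of the endothelial list 1.09 and 0.22, a contrast that was not tested. With the level of the adipocyte markers as a covariate the endothelial list had a median of 0.11 (camera adjusted p = 0.403). As all KO libraries lay above all WT libraries in that level, this setting cannot part fat content from genotype.

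The list of osteoblast and osteocyte markers had a median log2 fold change of 0.68 with 10 of 12 members higher (camera adjusted p = 2.70e-06; adjusted p = 0.344 with an estimated correlation). In it 5 of 12 passed edgeR's test adjusted over the list alone and 0 over all genes. Col22a1 stood at 66.6 ± 20.8 CPM in WT and 171 ± 66.5 CPM in KO, and Sp7, the osteoblast transcription factor osterix, at 38.6 ± 1.09 and 52.5 ± 7.61 CPM (SD, n = 3 each). Osteoclast markers had a median of 0.83 with 10 of 10 higher, 0 of them past the threshold adjusted over the list alone (camera adjusted p = 2.80e-06; adjusted p = 0.344 with an estimated correlation). Oscar, a receptor of osteoclasts, was at 4.06 and 10.1 CPM and Ocstamp, a cell fusion protein, at 3.42 and 8.15 CPM in WT and KO. The mean log2 CPM of osteoblast markers was 7.24, 7.19 and 6.27 in KO replicates 1 to 3 and 5.96 to 6.49 in WT, and that of osteoclast markers 6.68, 6.40 and 5.33 against 4.78 to 5.76. With the level of the adipocyte markers as a covariate, which cannot part fat content from genotype, the medians of these lists turned to -0.55 and -0.60.

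Genes of fibrous matrix and of matrix turnover were higher in KO as groups, while the matrix of cartilage itself did not pass its test. Fibrous matrix and small proteoglycans had a median log2 fold change of 0.26 with 16 of 24 members higher (camera adjusted p = 3.17e-06; adjusted p = 0.344 with an estimated correlation), and 0 passed edgeR's test adjusted over the list alone. The collagen I chains Col1a1 and Col1a2 had log2 fold changes of 2.02 (SE 0.57) and 1.80 (SE 0.49), with Col1a1 at 14371 and 10219 CPM in KO replicates 1 and 2, 3266 CPM in KO replicate 3 and 1132 to 3173 CPM in WT. KO replicates 1 and 2 were also the libraries highest in osteoblast markers, and whether the collagen I difference follows the share of bone was not tested. Col12a1 was at 53.1 and 75.1 CPM in WT and KO. Matrix proteases and their inhibitors had a median of 0.39 with 17 of 23 higher (camera adjusted p = 2.70e-06; adjusted p = 0.218 with an estimated correlation), 3 of them past the threshold adjusted over the list alone and 0 over all genes. Mmp2, a gelatinase, was at 64.1 ± 14.9 CPM in WT and 119 ± 14.9 CPM in KO, and Mmp16, a membrane-bound protease, at 9.89 ± 0.974 and 18.9 ± 5.49 CPM (SD, n = 3 each). The list of cartilage matrix and its regulators had a median of -0.16 with 13 of 20 members lower (camera adjusted p = 0.0864). Its members with the smallest p were Col9a3, a chain of collagen IX (311 and 209.5 CPM), and Comp, which binds collagen fibrils (4054 and 3122 CPM). Without WT replicate 3 this list had a median of -0.31 and a camera adjusted p of 1.96e-06, without KO replicate 2 the values were -0.25 and 0.0363, and with sex as a covariate -0.23 and 0.00626, and over the 24 alternatives 8 had an adjusted p under 0.05. With the adipocyte markers as a covariate the matrix protease list had a camera adjusted p of 0.144, and the median of the fibrous matrix list was -0.099. That covariate separates the genotypes, so these values cannot be ascribed to fat content.

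Ribosomal protein genes were slightly but widely lower in KO, with 49 of 54 members lower and a median log2 fold change of -0.19 (camera adjusted p = 5.56e-09; adjusted p = 0.344 with an estimated correlation). No member passed edgeR's test adjusted over the list alone (0 of 54), with Rps21 at 52.6 and 41.4 CPM and Rpsa at 40.9 and 33.7 CPM. Many ribosomal protein and glycolysis genes have near-identical copies elsewhere in the genome, so their counts are uncertain. Erythroid markers had a median of -0.59 with 6 of 6 lower (camera adjusted p = 5.01e-06; adjusted p = 0.344 with an estimated correlation), with Alas2 at 841 and 557 CPM and Epb4.2 at 118 and 81.7 CPM. Of the 13 fixed erythroid markers only these 6 were tested, without the globin genes. The mean log2 CPM of the 6 was 7.50, 6.67 and 8.04 in KO replicates 1 to 3 and 7.97 to 8.17 in WT. Cell cycle genes had a median of -0.14 with 24 of 26 lower, Cenpf and Cenpe leading at -0.31 and -0.23 (camera adjusted p = 0.000603; adjusted p = 0.707 with an estimated correlation), and the adjusted p was 0.578 without WT replicate 3, 0.518 without KO replicate 2, 0.0804 with sex as a covariate, where the median was -0.061, and 0.718 at a median of -0.029 without the 3 libraries high in muscle markers. Hypoxia and glycolysis genes had a median of -0.14 with 14 of 17 lower (camera adjusted p = 0.0295; adjusted p = 0.707 with an estimated correlation). Pdk1 was at -0.28 and Hk2 at 0.30, and without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 3 the list's adjusted p was 0.122, 0.640, 0.206 or 0.102, and it was 0.322 with the adipocyte markers as a covariate and 0.207 without the 3 libraries high in muscle markers. With the adipocyte markers as a covariate, which separates the genotypes, the medians of the erythroid and cell cycle lists turned to 0.42 and 0.15. In these 4 lists 0 members passed edgeR's test adjusted over the list alone.

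Skeletal muscle markers had a median log2 fold change of 0.77 with 18 of 18 higher (camera adjusted p = 0.0141; adjusted p = 0.804 with an estimated correlation), following the high level in 2 KO libraries and 1 WT library. Myh2 was at 5.81 ± 4.47 and 20.5 ± 19.5 CPM and Ttn at 263 ± 274 and 517 ± 411 CPM in WT and KO (SD, n = 3 each). The list's adjusted p was 0.180 without WT replicate 1, 0.773 without WT replicate 3, 0.749 without KO replicate 2 and 0.489 without KO replicate 3, and its median turned to -0.71 without the 3 libraries high in these markers. Smooth muscle and pericyte markers had a median of 0.37 with 7 of 9 higher (camera adjusted p = 0.0226; adjusted p = 0.344 with an estimated correlation), with Acta2 at 15.8 and 22.3 CPM and Rgs5 at 17.5 and 22.6 CPM. Its adjusted p was 0.0611 without WT replicate 2, 0.0521 without KO replicate 2, 0.229 without KO replicate 3 and 0.0783 with the adipocyte markers as a covariate. In both lists 0 members passed edgeR's test adjusted over the list alone.

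The other 14 lists, beside that of cartilage matrix, did not pass camera's adjusted threshold. Connective tissue fibroblast markers had a median of 0.23 (camera adjusted p = 0.0694), with Pdgfra at 0.77 past edgeR's threshold adjusted over the list alone and Col15a1 at -0.44. TGF-beta and BMP signalling had a median of -0.039 (camera adjusted p = 0.122), with Bmp7 at -0.60 and Id2 at -0.49. Superficial zone genes had a median of -0.12 (camera adjusted p = 0.191), with Tnc at 1.16 and Gdf5 at -0.50. The hypertrophy list had a median of 0.075 (camera adjusted p = 0.623), with Pth1r at 0.59 and with Ihh, at -0.57, as the 1 member past edgeR's threshold adjusted over the list alone. Immediate early genes had a median of 0.018 (camera adjusted p = 0.454), with Junb at 0.58 as the 1 member past that threshold and Egr1 at 0.78. Tendon and ligament markers had a median of -0.23, a mean of 0.11 and a test direction of lower (camera adjusted p = 0.623), with Col1a1 as the 1 member past that threshold and Fmod at -0.41. The unfolded protein response had a median of 0.089 (camera adjusted p = 0.191), with Sdf2l1 at 0.35 and Herpud1 at 0.17. Inflammatory mediators had a median of -0.041, a mean of 0.061 and a test direction of higher (camera adjusted p = 0.719), with Nos2 at 0.65 and Tnfaip6 at 0.32. The respiratory chain had a median of -0.014 (camera adjusted p = 0.719), with Atp5h at -0.17 and Sdhc at 0.16. Without WT replicate 2 this list's median was 0.12 with an adjusted p of 0.00171, and without WT replicate 1 it was -0.076 with an adjusted p of 0.0204. Of the blood and nerve lists, B cell markers were at a median of -0.0087 (Vpreb1 -0.82, Ebf1 0.27), T cell markers at -3.7e-05 (Cd4 0.41, Cd28 -0.36) and macrophage markers at 0.0076 with a mean of -0.0027 and a test direction of higher (Csf1r 0.37, Cd14 -0.49). Neutrophil and myeloid precursor markers were at a median of 0.026 (Mpo 0.70, Retnlg -0.34) and Schwann cell markers at -0.12 (Prx 0.21). The camera adjusted p of these 5 lists was 0.191, 0.719, 0.909, 0.814 and 0.368. The medians of the B cell, T cell and respiratory chain lists lay so near 0 that other scalings changed their sign.

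Single libraries decided several of these tests. Without KO replicate 2 the B cell list had a median of -0.68 (camera adjusted p = 5.60e-14), the T cell list of -0.27 (0.0251) and the fibroblast list of 0.25 (0.0367). Without WT replicate 3 the neutrophil list had a median of 0.23 (camera adjusted p = 0.0290) and TGF-beta and BMP signalling of -0.11 (0.00658), which was at -0.096 (0.0163) with sex as a covariate. Without WT replicate 1 the fibroblast list had a median of 0.25 (camera adjusted p = 0.0442), and without KO replicate 3 the unfolded protein response of 0.17 (0.0388).

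**Figure D2:**
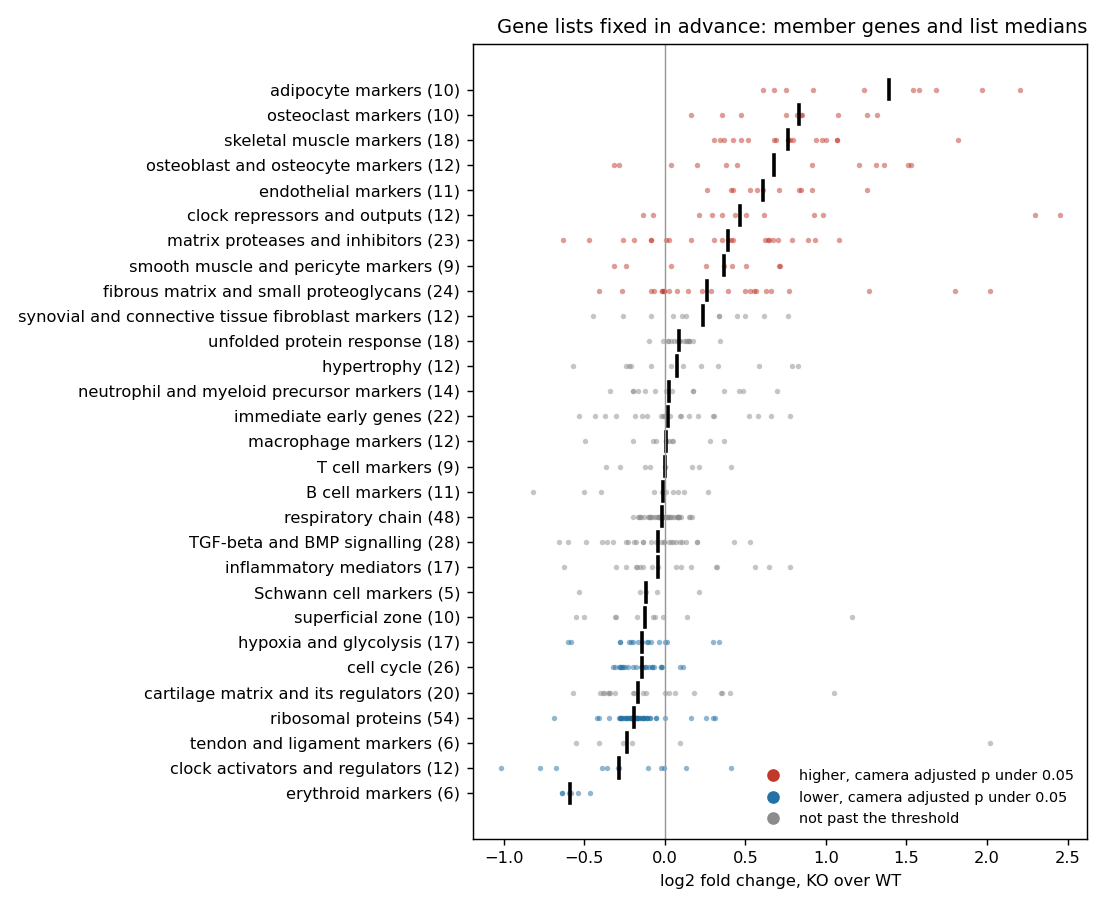
Log2 fold change, KO over WT, of every tested member (dots) and the median (bars) of the 29 lists, with the number of members in brackets. Red and blue mark the 9 higher and 5 lower lists past camera's adjusted threshold at the preset correlation, led by adipocyte markers at a median of 1.39.

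In all, 14 of 29 lists passed camera with the preset correlation of 0.01, 9 higher and 5 lower. With an estimated correlation 0 lists passed after adjustment, and with fry, which tests whether the genes of a list move one way on balance, 0 passed as well, while 4 lists had an unadjusted p under 0.05 in each of these tests. The 9 other ways to split the 6 libraries into 3 and 3 gave 8 to 16 lists with the preset correlation.

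**Figure D3:**
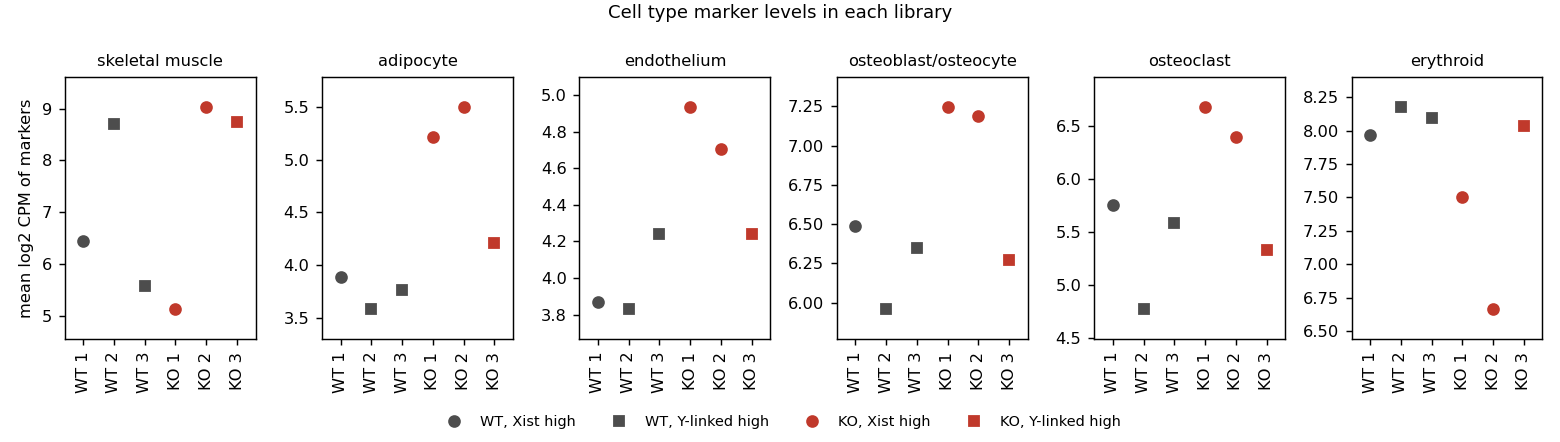
Mean log2 CPM of the markers of 6 cell types in each library, with WT in grey and KO in red, circles for libraries high in Xist and squares for those high in Y-linked genes. Skeletal muscle markers lie at 8.70 to 9.02 in WT 2, KO 2 and KO 3 and at 5.14 to 6.44 in the other 3 libraries, and in the adipocyte panel all 3 KO libraries, at 5.22, 5.50 and 4.21, lie above the WT libraries at 3.58 to 3.89.

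Genes that lie next to Cry2 on its chromosome were counted apart, since the DNA around a targeted gene can come from another mouse strain. Rbm45 lies on the same chromosome as Cry2, 91 tested genes away in the gene order of the GRCm38.p6 assembly, and Mapk8ip1, adjacent to Cry2 and named after its values were seen, had a log2 fold change of 0.89 (SE 0.20). Among the 400 nearest tested genes, 32 (8%) had an unadjusted p under 0.05, against 895 of 14645 (6.11%) elsewhere. The odds ratio was 1.34 (95% interval 0.895 to 1.93; Fisher's exact test, two-sided, p = 0.139), and 0 of these neighbours had an adjusted p under 0.05 by edgeR's quasi-likelihood test. In a window of 100 tested genes on each side the share was 10.5% (Fisher's exact test, p = 0.0166). With 400 tested genes on each side it was 7% (Fisher's exact test, p = 0.325). With 200 annotated genes on each side it was 9.18% (Fisher's exact test, p = 0.204). The windows other than that of 200 tested genes on each side were chosen after the data were seen.

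**Figure D4:**
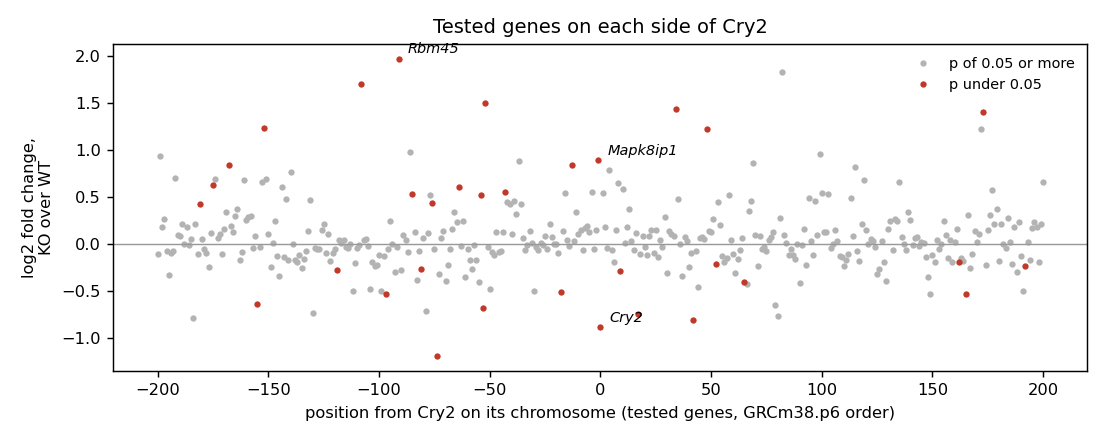
Log2 fold change, KO over WT, of the 200 tested genes on each side of Cry2, by their order on the chromosome in GRCm38.p6. Red dots are the genes with an unadjusted p under 0.05, among them Cry2 at -0.89, Rbm45 at 1.97 and Mapk8ip1, named after its values were seen, at 0.89.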

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

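Of the 29 settings other than the one reported, 18 were planned, and 11 were chosen after seeing the data: the sex, muscle, Ckm and adipocyte covariates, leaving out the 3 libraries high in muscle markers, 3 other forms of the quasi-likelihood fit and 3 other neighbour windows. Cry2 was lower in KO in 24 of 24 settings, with log2 fold changes of -1.01 to -0.78 without 1 library each. It passed its threshold in DESeq2 alone, at -0.88. The count of genes past the adjusted threshold was 50 in DESeq2, 1 (Rbm45) with no filter, 1 (Nr1d1) with the replicate block and 51 without the 3 libraries high in muscle markers, where fewer libraries were compared. Of the named genes 20, 1, 1 and 7 passed in these settings, and without 1 library each both counts ranged from 0 to 0. With the replicate number paired across genotypes 749 genes had an unadjusted p under 0.05 and 15 lists passed. The deviations from group means of WT and KO libraries with equal numbers had correlations of 0.15, 0.27 and -0.11. Those with unequal numbers ranged from -0.50 to 0.38, so whether the numbers mark pairs stays open. The count of lists was 12 to 15 without 1 library each, 0 with an estimated correlation and 0 with fry. The share of genes near Cry2 with an unadjusted p under 0.05 was 10.5% with 100 tested genes on each side and 7% with 400, and for no filter 4.25% against 5.47% elsewhere. For these results that did not hold the cause was not tested. The planned windows of 10, 20 and 40 Mb were not run, for lack of an annotation of mm9. List medians turned in these settings: skeletal muscle to -0.16 with 1 surrogate variable, -0.11 with muscle markers as a covariate and -0.71 without the 3 libraries, smooth muscle to a lower direction at a median of 0.076 without the 3 libraries, and the respiratory chain from -0.076 without WT replicate 1 to 0.12 without WT replicate 2. With the adipocyte markers as a covariate the medians were -0.099 for fibrous matrix, 0.15 for the cell cycle, -0.55 for osteoblast, -0.60 for osteoclast and 0.42 for erythroid markers, and 0.016 for the adipocyte list, where the setting removes what it measures. Every KO library was higher than every WT library in this covariate, so these turns cannot be ascribed to fat content. Beside these turns, the adipocyte covariate ended 5 list calls and made 4, the sex covariate ended 1 and made 2, the Ckm covariate 1 and 3, and leaving out the 3 libraries 2 and 5. The muscle covariate made 3, 1 surrogate variable 4, no filter 2 and the replicate block 1, and limma-voom ended 1. Of 634 list values 45 had another direction, 35 of them in lists not past the threshold, and 43 of 2008 values of named genes had another sign. The clock repressor and output list and the ribosomal list passed, in the same direction, in every setting that kept camera's preset correlation (22 of 22). The osteoblast and osteoclast lists (22 of 22) and the erythroid list (21 of 21) passed in every such setting as well, each with its direction turned in 1.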

Other observations

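The genes in this paragraph were chosen after their values were seen. Among the 50 genes that DESeq2 called, where edgeR's quasi-likelihood test called 0 with 930 at an unadjusted p under 0.05, were Mmrn2, an endothelial matrix protein (DESeq2 log2 fold change 0.98), the guidance receptor Robo4 (0.99), Arhgef15 (0.999), the basement membrane collagen Col4a2 (0.58) and the lipid droplet gene Plin4 (1.13). Tnfrsf11a, the receptor RANK of osteoclasts, was at 1.08, the cadherin Cdh11 at 0.79, Akap6 at 1.45, A2m at 1.85 and Tmem45b at 2.17. No group of these genes was tested as such. On the simulated counts, where 200 genes and the unfolded protein response list were changed, DESeq2 also made 47 calls among 14889 unchanged genes. Of cartilage genes, Col2a1 stood at 3045 and 3107 CPM, Acan at 1833 and 2080.5 CPM, Prg4 at 18012 and 15969 CPM and Cytl1 at 24887 and 19675 CPM in WT and KO.

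The tests in the paragraphs that follow were chosen only after the results were seen, apart from the 2 correlations of the adipocyte and endothelial markers within genotypes and the comparison of genes near Cry2, which was planned and whose reading was set afterwards.

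The clock repressors and outputs were higher in KO, with a median log2 fold change of 0.47. With sex as a covariate the median was 0.60 and with muscle markers as a covariate 0.46. These medians argue against sex or muscle RNA as the whole cause. Both fits also passed camera's threshold at the preset correlation, but the 9 other splits of the libraries passed it for 8 to 16 lists, so passing adds little. Without a covariate the list's call was lost with an estimated correlation (camera adjusted p = 0.111). Loss of the repressor CRY2 may raise these genes, but a different clock phase at tissue collection could also raise outputs and lower activators, and the labels give no collection time. The log2 ratio of Nr1d1 to Arntl was higher in every KO library than in every WT library by a gap of 1.13, less than the range within WT (1.96) and within KO (1.57), and these explanations cannot be told apart. Of the 10 splits of the libraries, too few for a share under 0.05, 1 had a list median as large, the real one, against a highest other of 0.41.

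The adipocyte and endothelial markers were higher in KO, above all in both female KO libraries. With sex as a covariate the adipocyte median was 1.13, against 1.39 without it. This argues against sex as the whole cause, although 1 male KO library is little to measure it by. The list was still past camera's threshold at the preset correlation, which adds little, as above. Without a covariate the adipocyte list's call was lost with an estimated correlation (camera adjusted p = 0.218). A larger share of marrow with its blood cells is argued against by the erythroid markers, whose mean log2 CPM lay at -0.58, -1.41 and -0.041 from the WT mean in KO replicates 1 to 3 where the adipocyte markers lay at 1.47, 1.76 and 0.47, while the neutrophil markers were at 0.47, -0.16 and -0.011. The mean log2 CPM of the B cell markers was 3.17, 5.34 and 4.42 in KO replicates 1 to 3 and 4.62 to 4.80 in WT. The B cell mean was above WT in KO replicate 2 and the neutrophil mean in KO replicate 1, so the argument rests on the erythroid markers. Of the 13 fixed erythroid markers 6 were tested, without the globin genes. Their mean pairwise correlation within genotypes was 0.95, so they are close to 1 measure. A varying share of fat tissue, or of marrow rich in fat and poor in blood cells, left on the cartilage is a candidate explanation, and for the endothelial markers the correlation with the adipocyte markers within genotypes passed the bound set before it was computed (Pearson r = 0.724, exact permutation p = 0.25; Spearman rho = 0.714, exact permutation p = 0.278; smallest p of the 36 orders 0.0278; r = 0.536 without KO replicates 2 and 3, the farthest), on few libraries. The adipocyte markers' own mean pairwise correlation was 0.410, where all but a small share of 1000 random lists of tested genes lay below 0.184. Over the cell type lists it ranged from -0.14 (Schwann cell) to 0.95 (erythroid). This left open whether a varying share or a change in gene levels underlies the adipocyte difference. The osteoblast and osteoclast markers were also highest in KO replicates 1 and 2, and whether the share of bone varied was not tested.

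Rbm45 and Mapk8ip1, the latter named after its values were seen, lie near Cry2 on its chromosome. DNA of another strain around the targeted gene could change them, by altered regulation or by how reads match the reference. The odds ratio of an unadjusted p under 0.05 among the 400 nearest tested genes was 1.34, with an interval of 0.895 to 1.93 that holds both no excess and a clear one. With 100 tested genes on each side it was 1.80 (1.08 to 2.86), and with 400 on each side 1.16 (0.857 to 1.53). These 2 windows were chosen after the data were seen, so the explanation stays open. Sequence variants were not analysed here, and a biological effect of genotype on these genes was not tested apart from it.

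The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The genotype split called 0 genes at an adjusted p under 0.05 by edgeR's quasi-likelihood test, which all 10 splits reach, and the highest other called 204. That split set WT replicates 1 and 3 and KO replicate 1 against the rest and points to a structure of the samples, their content of muscle transcripts. The split by sex called 5 genes, Xist and the 4 Y-linked genes. At an unadjusted p under 0.05 the genotype split gave 930 genes, 3 of the 10 splits as many or more, with 2087 as the highest other. It gave 14 lists, 2 of the 10 splits as many or more, with 16 as the highest other.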
